A study of Mus musculus with 63 samples.

How the data were processed

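Gene expression was measured on Illumina mouse BeadChip arrays in 63 cultures of 7 embryonic stem cell lines of the TT2 background, male per the labels: 2 wild-type lines, 2 lines without Jmjd1a (gene symbol Kdm3a, a histone H3 lysine 9 demethylase), 2 lines without G9a (gene symbol Ehmt2, a histone H3 lysine 9 methyltransferase) and 1 line made from G9a KO1 by putting G9a back. The Y-linked Eif2s3y was at the floor in all 3 normoxia cultures of WT2 and above it in those of the other 6 lines. Each line was seeded at 3 densities (2, 4 and 6, in units of 100000 cells per 6 cm plate), and each density was given 3 exposures. Exposures began 18 h after plating and were 24 h of normoxia (21% oxygen), 20 h of normoxia followed by 4 h of hypoxia (1% oxygen), or 24 h of hypoxia. Per the labels, total RNA was labelled from 500 ng with an Illumina kit. The groups were genotype by exposure, with 6 cultures of 2 lines in each group of the wild-type and knockout genotypes and 3 cultures of 1 line in each reconstituted group.

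The values used were the deposited intensity values of 25697 probes on a linear scale, as processed by the authors. BeadStudio is named in the notes of the authors, and its version and the processing steps are not given in the sources used here. Every array had a lowest value of 20, shared by over 50% of its probes on most arrays, and the highest value was 41907. A companion table of 63 signal columns and 63 detection p columns named its columns by chip and position. No label gave a sample's chip position, so that table was not used here, and background correction from it (neqc) and filters on detection p, both planned, were not run. The planned use of the chip as a random block could not be run for the same reason.

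Intensities were put on the log2 scale, quantile normalized with limma 3.58.1 in R 4.3.3, and given a common floor of 4.32. A probe was kept if it was above the floor in all 3 cultures of at least 1 line and exposure, which kept 12754 probes. A further 10926 probes were at the floor on all arrays. The gene names of the probes came from the array annotation: 23978 probes had 1 gene symbol and 1719 had none, and the Entrez identifiers of 23962 of the named probes matched a gene in the reference table. The probe with the highest mean stood for each gene, which left 8740 genes for testing, 5953 of them above the floor on all 63 arrays. For a gene at the floor on every array of a group, the fold change was computed against the lowest value above the floor on the same arrays and is given as "at least". Where only part of a group's arrays were at the floor, the difference is given as computed and can understate the change. Total intensity per array ran from 6974757 to 8408782, and 40.3 to 46.4% of probes per array were above the floor. Precision is limited by the number of cultures and lines, by the differences between array sets and, for weak transcripts, by the floor. Arrays of 1 line and exposure correlated at 0.941 to 0.997, and no pair of arrays held identical values.

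Hypoxia was tested with limma on all 63 arrays, with a mean for each of the 21 combinations of line and exposure and a term for density. The reconstituted line was compared with its parent in the same fit, which compares 1 line with 1 line. Knockouts were compared with wild-type on the mean of each line, 2 lines against 2, because cultures of 1 line are not independent of each other; the difference between genotypes in the 24 h response was tested in the same way. Density was tested as a linear term over the 21 combinations. All p values are two-sided and adjusted by Benjamini and Hochberg over the 8740 genes of a comparison, with a threshold of 0.05. Values are log2 differences ± SE unless a standard deviation (SD) is named. Cultures of 1 line at the same density on other exposures correlated after removal of group means with a median r of 0.236 and a lowest r of -0.161, so densities were not treated as pairs.

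A total of 23 gene lists were written before the data were examined: glycolysis, hypoxia-inducible genes, histone H3K9 methylation enzymes and readers, germline genes, 2-cell embryo genes, pluripotency, ectoderm, mesoderm, endoderm, trophectoderm, fibroblast feeder cells, stimulators and inhibitors of angiogenesis, imprinted genes, G2 and mitosis, DNA replication, p53 targets, the integrated stress and unfolded protein response, cholesterol synthesis, oxidative phosphorylation, ribosome biogenesis and nucleolus, metallothioneins, and Y-linked genes. Members past the threshold are counted over all genes and with p adjusted over the list alone. Lists were tested against the other genes with camera in limma, with an inter-gene correlation preset at 0.01 and again with an estimated correlation, and adjusted over the 23 lists. The groups, comparisons, lists, tests and alternatives were chosen before the data were examined, except where stated.

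The genes named in the text follow a rule fixed with the lists: Kdm3a and Ehmt2 in every group; in each comparison up to 6 genes with the highest and 6 with the lowest log2 difference among those past the threshold that moved the same way in every line; and up to 4 members with the smallest adjusted p of each list described. Genes named outside this rule are said to have been chosen after their values were seen.

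Array totals stepped between sets of 8 consecutive arrays of the deposit order. The sum of squares of log2 totals within sets was 0.0104 of 0.354 when sets began at the first array, and 0.0490 to 0.0960 at the other starting points. The companion table names 8 chips, 7 of them with 8 arrays. The sets were therefore taken as array batches, and each comparison was fitted again in limma with the array set as a block (genotype and exposure means, line within genotype and density, with line as a random block between genotypes). This fit, the leaving out of 1 array with a second lowest value of 21.9, and the naming of genes that passed with and without the array-set block were chosen after the data were seen.

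Other alternatives were scaling to the 75th percentile, the deposited values with no further normalization, no filter on dim probes, only probes above the floor on every array, the mean of all kept probes of a gene, eBayes with trend and robust settings, density left out, line and density pairs as a block, only the arrays compared, cultures as the replicates between genotypes, other scales of density, and leaving out each line or density. Other splits of the samples were counted for every comparison with seed 20240.

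The procedure was tested on simulated data of 8740 genes, of which 200 were changed. Simulated array-set effects were drawn with the spread of the real set means. Those means also hold differences between lines, genotypes and exposures, so the simulated effects can be too large. Without simulated array-set effects, the 24 h wild-type comparison recovered 98.5% of the genes changed 2-fold and called 15 unchanged genes, and the line means of G9a knockout against wild-type recovered 47.8% and called 6. With simulated array-set effects these line means recovered 0% of the genes changed 1.5-fold, 2-fold or 4-fold, as did those of Jmjd1a knockout against wild-type and of the G9a difference in response. The blocked fit of that difference recovered 93.9% of the genes changed 4-fold and called 4 unchanged genes. With simulated array-set effects, the 24 h comparison in Jmjd1a knockout cells called 1427 unchanged genes without the block and 7 with it. Between knockout and wild-type in normoxia the blocked fit called 206 (G9a) and 211 (Jmjd1a) unchanged genes without and 163 and 191 with simulated array-set effects, and reconstituted against parent called 1662 without the block even in the absence of array-set effects, since line and genotype coincide there. Genes called in both of its fits still held 72 unchanged genes (51.8% of the calls) without and 57 (46.3%) with simulated array-set effects. Counts of genes that passed in both fits are given beside most others, and for reconstituted against parent they do not remove differences between single lines. The simulation of Jmjd1a knockout against wild-type, and the count of each list's genes at the floor in wild-type cells, were added after the results were seen. Of 200 simulated unchanged lists, 7 had a camera p under 0.05. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15, and statmod 1.5.0 was used for random blocks.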

Results

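Expression was measured in 63 cultures of mouse embryonic stem cells to ask what Jmjd1a and G9a, which remove and add methyl groups at lysine 9 of histone H3 and respond to low oxygen, do in stem cells with and without hypoxia. Wild-type, Jmjd1a knockout and G9a knockout cells were each represented by 2 lines and 6 cultures per exposure, and G9a knockout cells with G9a put back (reconstituted) by 1 line and 3 cultures per exposure. The median share of probes above the floor was 43.0% per array. Array totals ran from 6974757 to 8408782 and moved in steps of 8 arrays, and 6 of these 8 sets held arrays of 2 lines. The first principal component of 5953 genes held 56.5% of the variance. Array set explained 98.6% of that component, line 82.8% and exposure 0.693%. Between neighbouring arrays of 1 line, a median of 533 genes differed by over 1 log2 unit in the 5 pairs that crossed a set boundary and a median of 8 in the 37 pairs that did not. Exposure explained 74.3% of the second component, which held 9.67% of the variance.

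**Figure D1:**
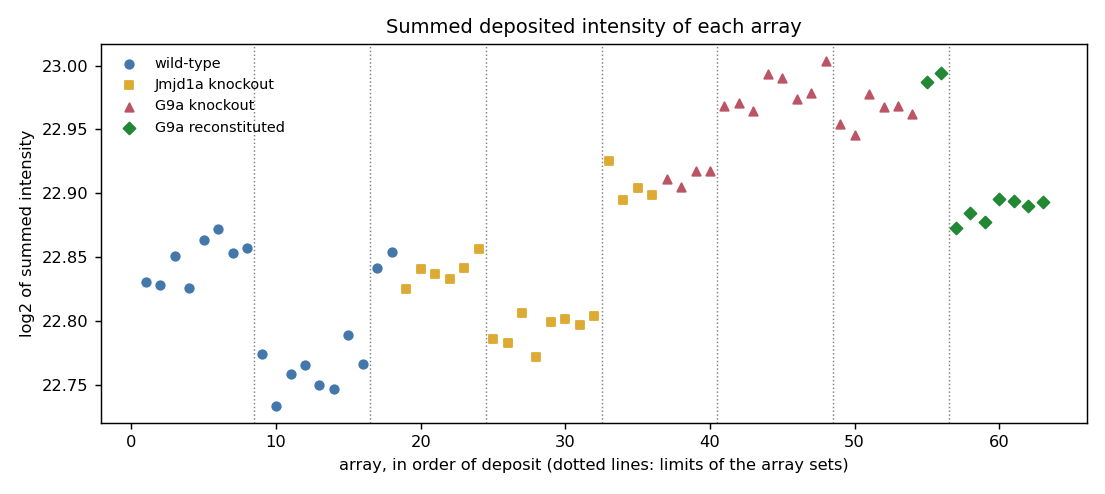
Log2 of the summed deposited intensity of each of the 63 arrays in deposit order, with dotted lines at the limits of sets of 8 arrays. Totals ran from 6974757 to 8408782 and stepped at the set limits.

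The transcripts of the altered genes were read first. Kdm3a, which encodes Jmjd1a, was at 10.40 ± 0.24 log2 intensity in wild-type normoxia, 10.91 ± 0.12 after 4 h and 10.74 ± 0.19 after 24 h of hypoxia (SD, n = 6 cultures each). At this probe it was at the floor of 4.32 in all 18 cultures without Jmjd1a, while a further Kdm3a probe was above the floor in each of them. In G9a knockout normoxia it was at 10.81 ± 0.06 (SD, n = 6) and in reconstituted normoxia at 10.68 ± 0.11 (SD, n = 3). Ehmt2, which encodes G9a, was at 8.66 ± 0.22, 9.04 ± 0.23 and 9.62 ± 0.22 in wild-type normoxia, 4 h and 24 h of hypoxia, and at 8.44 ± 0.07, 8.89 ± 0.20 and 9.14 ± 0.21 in Jmjd1a knockout cells (SD, n = 6 each). G9a knockout cells still gave signal at the Ehmt2 probe, at 7.80 ± 0.27, 8.43 ± 0.11 and 8.62 ± 0.30 (SD, n = 6), and reconstituted cells gave 8.20 ± 0.42, 9.21 ± 0.10 and 9.43 ± 0.22 (SD, n = 3). A further Ehmt2 probe also stayed above the floor in these cells. Where these probes lie relative to the altered part of the gene was not known, so they cannot tell an altered transcript from an intact one.

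**Figure D2:**
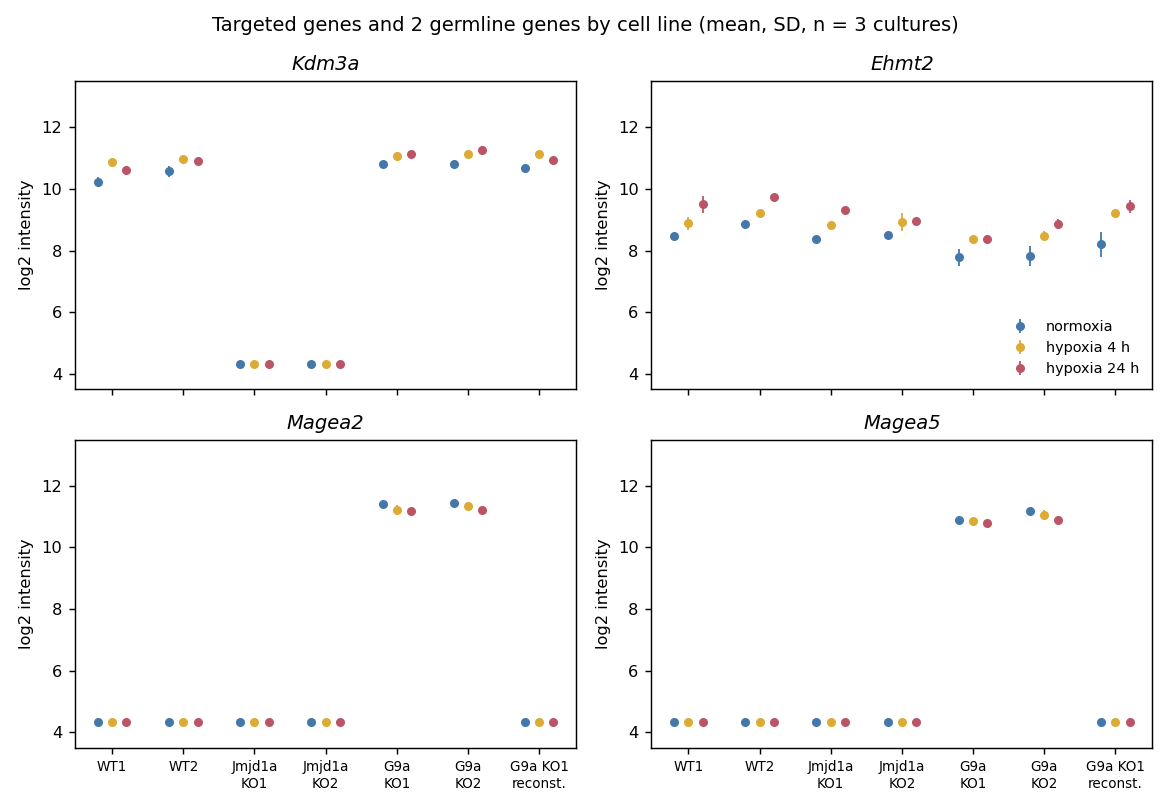
Log2 intensity of Kdm3a, Ehmt2, Magea2 and Magea5 by line and exposure, as mean ± SD of 3 cultures. The Kdm3a probe shown lay at the floor of 4.32 in both Jmjd1a knockout lines, and Magea2 and Magea5 lay above the floor in both G9a knockout lines and at it in the other lines.

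The response of wild-type cells to 24 h of hypoxia gives the reference for the knockouts. Adm, a vasodilator peptide, rose by 3.77 ± 0.19 and the hypoxia-inducible Ndrg1 by 3.03 ± 0.21 log2 (SE, n = 6 and 6 cultures of 2 lines). Cyp2s1, a cytochrome P450, rose by 3.03 ± 0.12, Bdnf, a neurotrophin, by 2.78 ± 0.12 and the lactate exporter Slc16a3 by 2.77 ± 0.12. In normoxia Slc16a3 was at the floor on 4 of 6 arrays, Adm on 3 and Bdnf on 1, so their rises can be understated. Edn2, which encodes an endothelin, was at the floor in normoxia and at least 6.88-fold higher. Crygd, a crystallin, fell by 1.73 ± 0.14, the inhibin subunit gene Inhbb by 1.49 ± 0.16 and the histone gene H3c7 by 1.48 ± 0.15. Tbx3, a transcription factor of naive pluripotency, fell by 1.43 ± 0.12 and Ccdc114 by 1.40 ± 0.12. Of 8740 genes, 1568 rose and 1650 fell at an adjusted p under 0.05, and 1319 and 1355 did so with the array-set block as well.

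Of 32 hypoxia-inducible genes, 27 rose, 1 fell and 4 did not pass the test after 24 h, with the same counts adjusted over the list alone (camera adjusted p = 1.2e-17, and 2.8e-05 with an estimated correlation). Their median was 0.66 log2, or 0.58 with genes at the floor set at their bound. Plod2, a collagen hydroxylase, rose by 1.91 ± 0.07, the mitochondrial Fam162a by 1.31 ± 0.07 and the transferrin receptor Tfrc by 0.78 ± 0.05. Of 19 glycolysis genes, 17 rose and none fell, the same counts as adjusted over the list alone (adjusted p = 2.0e-16, and 9.7e-04 with an estimated correlation). Among them Pfkl, a phosphofructokinase, rose by 1.31 ± 0.06, the glucose transporter Slc2a1 by 1.15 ± 0.07 and Aldoc, an aldolase, by 1.43 ± 0.09. Cholesterol synthesis followed, with 10 of 17 genes up and none down, over all genes and adjusted over the list alone (adjusted p = 5.0e-06, and 0.0119 with an estimated correlation). Cyp51 was at 0.83 ± 0.09 and Sqle at 0.58 ± 0.06. Of 17 stimulators of angiogenesis, 10 rose and 2 fell (11 and 2 adjusted over the list alone; adjusted p = 1.4e-04, and 9.7e-04 with an estimated correlation). Anxa2, which takes part in plasmin formation, rose by 2.48 ± 0.11 and the chemokine Cxcl12 by 1.18 ± 0.09, and Vegfc, a growth factor of lymphatic vessels, fell by 0.77 ± 0.09.

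Markers of early lineages also moved after 24 h. Of 9 ectoderm genes, 7 rose and 1 fell, also adjusted over the list alone (adjusted p = 1.6e-04, and 9.7e-04 with an estimated correlation). Otx2, Fgf5 and Pou3f1, which mark the formative epiblast, rose by 1.52 ± 0.09, 1.32 ± 0.11 and 1.09 ± 0.08. Of 11 mesoderm genes, 5 rose, also adjusted over the list alone (adjusted p = 0.0214, and 0.0262 with an estimated correlation; 0.0573 with the array-set block). Eomes rose by 2.40 ± 0.21 and Msx1 by 1.57 ± 0.13. Of 16 trophectoderm genes 4 rose and 1 fell (the same adjusted over the list alone; adjusted p = 0.0486, 0.190 with an estimated correlation and 0.0573 with the array-set block), led by the keratin Krt19 at 2.19 ± 0.15. Of 30 pluripotency genes, 5 rose and 10 fell (5 and 12 adjusted over the list alone; adjusted p = 0.0650, and 0.0350 with the array-set block). Dppa3, a naive marker, fell by 0.82 ± 0.07, and Upp1, a uridine phosphorylase, rose by 0.97 ± 0.07.

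Among genes of the integrated stress and unfolded protein response, 13 of 24 fell and 2 rose, also adjusted over the list alone (adjusted p = 0.00191, lost at adjusted p = 0.190 with an estimated correlation). Chac1, a glutathione-degrading enzyme, was at -1.36 ± 0.14, Herpud1 at -0.91 ± 0.10 and asparagine synthetase, Asns, at -0.51 ± 0.07. Of 18 histone H3K9 methylation enzymes and readers, 6 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.0716, and 0.0415 with the array-set block). The demethylase genes Kdm4b, Kdm4c and Kdm3a rose by 0.96 ± 0.09, 0.86 ± 0.09 and 0.34 ± 0.06, and Ehmt2 by 0.96 ± 0.09 (adjusted p = 1.4e-11).

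The other 13 lists gave no camera call at 24 h in wild-type cells. Counts adjusted over the list alone were the same unless given. Of 31 germline genes 8 rose and 5 fell, and of the 15 genes of the 2-cell embryo 1 fell (0 in limma adjusted over the list alone). Of 16 endoderm genes 6 rose and 3 fell, and of 9 fibroblast feeder genes 3 rose. Inhibitors of angiogenesis had 5 up and 3 down of 11 (6 and 4 adjusted over the list alone), with a median of 0.11 and a mean of -0.02. Of 15 imprinted genes 5 rose and 3 fell, with Peg10 at 1.27 ± 0.09. Of 18 G2 and mitosis genes 3 rose and 2 fell, of 21 DNA replication genes 4 rose and 3 fell, and of 20 p53 targets 4 rose and 1 fell. Oxidative phosphorylation had 7 of 44 genes down (5 adjusted over the list alone), as for Atp5o at -0.59 ± 0.06. Ribosome biogenesis and nucleolus had 4 up and 5 down of 24. None of 3 metallothioneins and 4 Y-linked genes passed the test.

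Within single array sets, 98.4% of the 3218 called genes moved the same way in WT1 (2 arrays against 3) and 96.4% in WT2 (1 against 3).

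**Figure D3:**
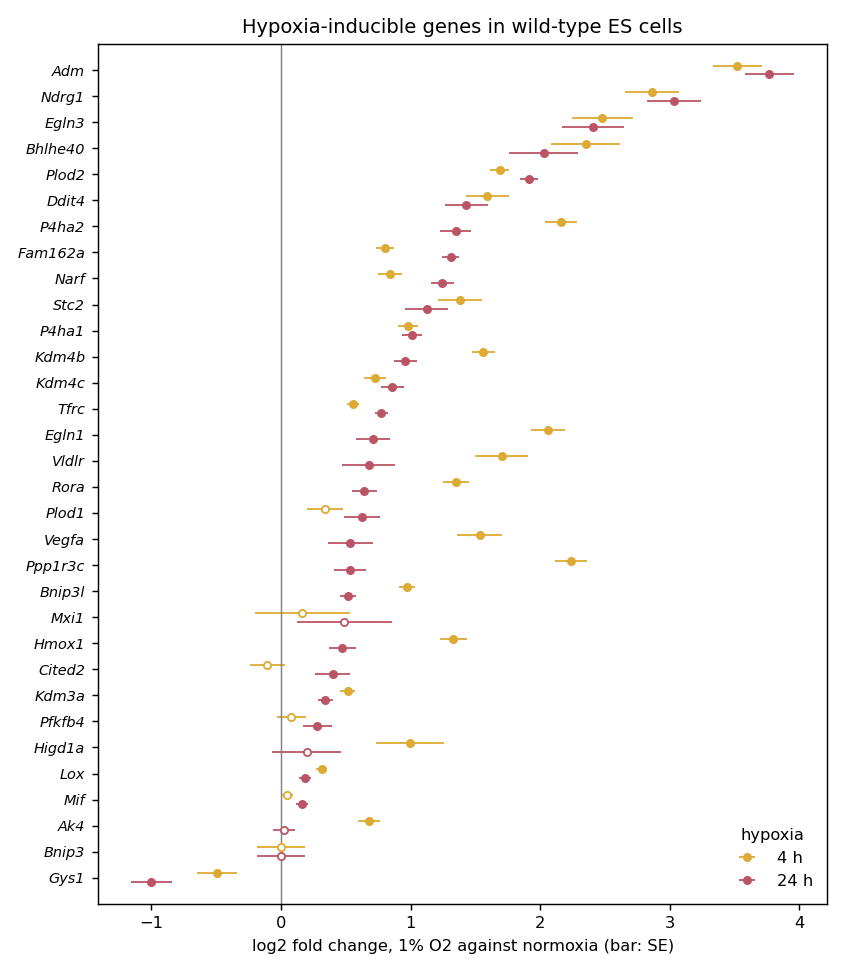
Log2 change ± SE of 32 hypoxia-inducible genes in wild-type cells after 4 h and 24 h of hypoxia against normoxia, with filled points for an adjusted p under 0.05 and open points for others. At 24 h 27 rose and 1 fell, and at 4 h 25 rose and 1 fell.

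After 4 h of hypoxia, wild-type cells had 1247 genes up and 1123 down, and 1244 and 1116 were called with the array-set block as well. Adm rose by 3.52 ± 0.19, Ndrg1 by 2.87 ± 0.21 and Cyp2s1 by 2.80 ± 0.12 log2 (SE, n = 6 and 6). Bdnf rose by 2.59 ± 0.12 and Espn, an actin-bundling protein gene, by 2.52 ± 0.10. Chac1 fell by 1.76 ± 0.14, Rapgef6 by 1.32 ± 0.14 and the glycine transporter Slc6a9 by 1.25, and H3c7 reached the floor and was at least 3.35-fold lower. Kdm3a rose by 0.51 ± 0.06 (adjusted p = 2.2e-09) and Ehmt2 by 0.39 ± 0.09. Of the hypoxia-inducible genes 25 of 32 rose and 1 fell (26 and 1 adjusted over the list alone; median 0.99, or 0.91 with genes at the floor set at their bound; adjusted p = 3.1e-32, and 3.9e-08 with an estimated correlation). Ppp1r3c, a regulator of glycogen, rose by 2.24 ± 0.12. Glycolysis had 16 of 19 genes up over all genes and adjusted over the list alone (adjusted p = 1.4e-17, and 6.8e-04 with an estimated correlation), with the hexokinase Hk2 at 1.03 ± 0.06. Stimulators of angiogenesis had 8 of 17 genes up, also adjusted over the list alone (adjusted p = 3.8e-05 with an estimated correlation), with the VEGF receptor gene Flt1 at 1.73 ± 0.16.

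Lineage markers had begun to move at 4 h. Ectoderm had 5 of 9 genes up (6 adjusted over the list alone; adjusted p = 0.00117 with an estimated correlation) and mesoderm 5 of 11 (7 adjusted over the list alone; adjusted p = 0.0105 with an estimated correlation), with Otx2 at 1.11 ± 0.09 and Eomes at 2.10 ± 0.21. Trophectoderm had 8 up and 1 down of 16, endoderm 6 up of 16, cholesterol synthesis 6 up and 2 down of 17 and the stress response list 12 down and 2 up of 24. Adjusted over the list alone the last had 15 down and the others the same counts. These 4 calls were lost at adjusted p = 0.0575, 0.0742, 0.225 and 0.0910 with an estimated correlation. Inside array sets 98.9% of the called genes moved the same way in WT1 and 99.2% in WT2. With 1 line left, fewer genes passed, 1407 without WT1 and 1249 without WT2.

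Between 4 h and 24 h 1061 genes were higher and 1236 lower, and 853 and 906 were so with the array-set block as well. Mzb1, a plasma cell chaperone gene, was higher by 2.10 ± 0.15, the endothelial receptor gene Robo4 by 1.82 ± 0.13 and the interferon-inducible Gbp2 by 1.53 ± 0.10 log2 (SE, n = 6 and 6). Aqp9, an aquaporin, was at the floor at 4 h and at least 2.62-fold higher at 24 h. Crygd fell by 1.80, Ppp1r3c by 1.70 ± 0.12, the metallothionein Mt2 by 1.55 ± 0.25, the immediate early gene Egr4 by 1.55 ± 0.09 and the oxygen sensor Egln1 by 1.35 ± 0.13. Of the hypoxia-inducible genes 5 were higher and 14 lower at 24 h (6 and 14 adjusted over the list alone; adjusted p = 0.0371, lost at adjusted p = 0.274 with an estimated correlation). Ehmt2 rose by a further 0.57 ± 0.09, while the pluripotency genes Esrrb and Tbx3 fell by 0.86 ± 0.08 and 1.17 ± 0.12.

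Further lists moved between 4 h and 24 h with the preset correlation. G2 and mitosis had 7 of 18 genes higher, p53 targets 7 higher and 1 lower of 20 (8 and 1 adjusted over the list alone), cholesterol synthesis 7 of 17 higher, oxidative phosphorylation 6 of 44 lower and metallothioneins 2 of 3 lower. All 5 calls were lost with an estimated correlation, at adjusted p = 0.187 for the first 3, 0.243 and 0.190. Inside array sets 97.6% of the called genes moved the same way in WT1 and 96.6% in WT2, and without WT2 1478 genes passed.

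In Jmjd1a knockout cells 24 h of hypoxia raised 1960 genes and lowered 2394, of which 630 and 497 also passed with the array-set block. Hypoxia genes rose without the demethylase: Adm by 3.37, Ndrg1 by 2.94, the oxygen sensor Egln3 by 2.78 and Plod2 by 2.33 ± 0.07 log2 (SE, n = 6 and 6), while Csta2, a cysteine protease inhibitor gene at the floor in normoxia, was at least 10.3-fold higher. Nupr1, a stress-induced gene, fell by 1.96, the growth factor Fgf17 by 1.72 and Chac1 by 1.60. Of the hypoxia-inducible genes 24 of 32 rose and 1 fell (adjusted p = 3.0e-04 with an estimated correlation), and of the glycolysis genes 16 of 19 rose and 1 fell (0.00617 with an estimated correlation). Cholesterol synthesis had 14 of 17 genes up (adjusted p = 0.00617 with an estimated correlation), as for Msmo1 at 1.17 ± 0.10. Pluripotency genes fell in 16 of 30 cases and rose in 4 (6 adjusted over the list alone; adjusted p = 0.00607, and 0.0257 with an estimated correlation), with Esrrb at -1.36 ± 0.08 and Dppa3 at -0.97 ± 0.07. Ehmt2 rose by 0.70 ± 0.09. Ectoderm had 6 up and 1 down of 9, mesoderm 3 up of 11 and stimulators of angiogenesis 7 up and 3 down of 17 (adjusted p = 0.0147, 0.0257 and 0.0257 with an estimated correlation; 0.0757, 0.0563 and 0.0615 with the array-set block). The stress response had 17 down and 5 up of 24 (lost at adjusted p = 0.188 with an estimated correlation). Counts other than that for pluripotency were the same adjusted over the list alone. No set held both 24 h and normoxia arrays of the same Jmjd1a knockout line; the blocked count was 1327, and without JMJD1a KO2 2550 genes passed.

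After 4 h, Jmjd1a knockout cells had 1184 genes up and 1464 down, and 1085 and 1210 were called with the array-set block as well. With the deposited values left unscaled 1384 were up and 1200 down, so the excess of lower genes turned with the scaling. Adm rose by 3.82, Egln3 by 3.23, Ndrg1 by 3.06, the collagen hydroxylase P4ha2 by 2.40 ± 0.12 and Ppp1r3c by 2.31 log2, and Chac1 fell by 2.25 ± 0.14, Trib3 by 1.53 and Ddit3 by 1.28, all 3 of the last being stress response genes (SE, n = 6 and 6). Of the hypoxia-inducible genes 24 of 32 rose and 1 fell, of the glycolysis genes 15 of 19 rose, of the ectoderm genes 5 of 9 rose and 1 fell, and of the stimulators of angiogenesis 7 of 17 rose (8 and 2 down adjusted over the list alone, and the same counts for the first 3), each at an adjusted p of at most 0.00916 with an estimated correlation. Trophectoderm had 6 up and 1 down of 16 (7 and 1 adjusted over the list alone), the stress response 11 down and 2 up of 24 (12 and 2) and cholesterol synthesis 9 up and 2 down of 17 (10 and 2). These 3 calls were lost at adjusted p = 0.0915, 0.206 and 0.111 with an estimated correlation. Inside array sets 99.7% of called genes moved the same way in JMJD1a KO1 and 98.1% in JMJD1a KO2. With 1 line left, 1606 genes passed without JMJD1a KO1 and 1490 without JMJD1a KO2.

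G9a knockout cells answered 24 h of hypoxia with 1841 genes up and 2159 down, of which 856 and 713 also passed with the array-set block. Adm rose by 4.01 ± 0.19 and the interferon-inducible GTPase genes Ifi47 and Gbp2 by 3.74 ± 0.23 and 2.97 ± 0.10 log2 (SE, n = 6 and 6). Ndrg1 rose by 3.38, Bdnf by 3.34 and Anxa2 by 2.97 ± 0.11. The transporter gene Slc47a1 fell by 2.11 ± 0.11 and Igfbp7 by 1.99 ± 0.16. Of the 2-cell embryo genes, which are switched on in the early embryo, 12 of 15 rose and 2 fell, also adjusted over the list alone, and 10 rose with the array-set block as well (median 0.71; adjusted p = 7.3e-06, lost at adjusted p = 0.165 with an estimated correlation). Pramel31 rose by 1.64 ± 0.15, Arg2 by 1.47 ± 0.11, Tdpoz4 by 0.97 ± 0.10 and Zfp352 by 0.74 ± 0.08. Of the p53 targets 13 of 20 rose and 2 fell (14 and 2 adjusted over the list alone; adjusted p = 0.00756 with an estimated correlation), with the cell cycle inhibitor Cdkn1a at 0.69 ± 0.07 and Phlda3 at 0.96 ± 0.09. Hypoxia-inducible genes had 23 up and 2 down of 32, glycolysis 17 up and 1 down of 19 (18 and 1 adjusted over the list alone), ectoderm 6 up and 1 down of 9 and stimulators of angiogenesis 9 up and 2 down of 17, each at an adjusted p of at most 0.00610 with an estimated correlation. Ectoderm lost its call with the array-set block (adjusted p = 0.0507). Y-linked genes had 3 of 4 down, with Zfy1 at -0.75 ± 0.09 (lost at adjusted p = 0.212 with an estimated correlation). Kdm3a rose by 0.38 ± 0.06 and Ehmt2 by 0.82. No line had normoxia and 24 h arrays in 1 set; the blocked count was 1732, and without G9a KO1 2469 genes passed.

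After 4 h G9a knockout cells had 1414 genes up and 1522 down, of which 570 and 374 also passed with the array-set block. Adm rose by 3.72, Ndrg1 by 2.68, P4ha2 by 2.40 and the enolase Eno2 by 2.10 ± 0.16. Gadd45g fell by 1.79, Chac1 by 1.69, the Nodal antagonist Lefty1 by 1.44 and Fgf4 by 1.35 ± 0.12 log2 (SE, n = 6 and 6). Hypoxia-inducible genes had 24 up and 1 down of 32, glycolysis 13 up and 1 down of 19 (14 and 1 adjusted over the list alone), ectoderm 7 up of 9, stimulators of angiogenesis 9 up and 1 down of 17 (10 and 1 adjusted over the list alone) and trophectoderm 7 up of 16, each at an adjusted p of at most 0.0319 with an estimated correlation. G2 and mitosis genes fell in 11 of 18 cases and rose in 1 (adjusted p = 0.00511, and 0.0322 with an estimated correlation; 3 fell with the array-set block), as for the mitotic kinase Aurka at -0.58 ± 0.08 and Cdk1 at -0.35 ± 0.06. Germline genes had 9 down and 3 up of 31, endoderm 6 up and 2 down of 16 (8 and 2 adjusted over the list alone), the stress response 12 down and 3 up of 24 and metallothioneins 2 of 3 up. These calls were lost at adjusted p = 0.0801, 0.0699, 0.212 and 0.149 with an estimated correlation. Inside 1 array set 94.6% of called genes moved the same way in G9a KO1 (1 array against 3). The blocked count was 1045, and without G9a KO2 1893 genes passed.

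The reconstituted line had 2059 genes up and 1337 down after 24 h, and 715 and 473 passed with the array-set block as well. Bdnf rose by 3.47, Anxa2 by 3.33 ± 0.15, Ndrg1 by 3.15, Adm by 3.09 ± 0.27 and Krt19 by 3.03 ± 0.21 log2 (SE, n = 3 and 3 cultures of 1 line). Hypoxia-inducible genes had 23 up and 1 down of 32 (24 and 1 adjusted over the list alone), glycolysis 15 up and 1 down of 19 (15 and 2), stimulators of angiogenesis 9 up and 1 down of 17 and cholesterol synthesis 14 up of 17, each at an adjusted p of at most 0.0268 with an estimated correlation. Cyp51 rose by 1.33 ± 0.12 and Sqle by 0.88 ± 0.09. Ehmt2 rose by 1.24 ± 0.13. Of the genes with the lowest values, the translation factor gene Eif1ax, at least 4.59-fold lower, was at -0.28 with the array-set block, and Zfp987 (-1.99 ± 0.76, adjusted p = 0.0347) was at 0.07. After 4 h 2005 genes rose and 1262 fell, 624 and 325 with the array-set block as well. Ndrg1 rose by 3.06, Adm by 3.05, Flt1 by 2.86 ± 0.22 and P4ha2 by 2.38 ± 0.17, and of the hypoxia-inducible genes 25 rose and 2 fell (26 and 2 adjusted over the list alone; adjusted p = 4.5e-05 with an estimated correlation). Stimulators of angiogenesis had 7 of 17 up (8 adjusted over the list alone; 0.00571 with an estimated correlation). Glycolysis had 12 up and 1 down, ectoderm 5 up and 2 down of 9, trophectoderm 10 up and 1 down of 16 and cholesterol synthesis 7 up and 1 down of 17. Adjusted over the list alone ectoderm had 6 and 2, cholesterol synthesis 8 and 1 and the others the same counts. These calls were lost at adjusted p = 0.0674, 0.0667, 0.0674 and 0.230 with an estimated correlation. The blocked counts were 1743 at 24 h and 1350 at 4 h. Inside 1 array set, with 1 normoxia array, 85.3% of the called genes moved the same way at 24 h and 82.4% at 4 h. With the deposited values left unscaled the share of called genes that were higher went from 60.6 to 45.0% at 24 h and from 61.4 to 45.4% at 4 h. In limma on the 6 arrays compared alone 0 genes passed at either time, with 2461 and 2237 at an unadjusted p under 0.05, against 4077 and 4007 in the fit of all arrays. Without density 2 the counts were 2118 and 1810, and without density 4 1966 and 1806.

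Jmjd1a knockout lines were compared with wild-type to ask which genes depend on the demethylase. Kdm3a itself was, at the probe that stands for it, at least 62.1-fold lower in normoxia (adjusted p = 0.00736), 88.2-fold lower after 4 h (adjusted p = 2.8e-04) and 80.5-fold lower after 24 h (adjusted p = 0.00325), each a lower bound from 2 lines against 2 (n = 6 and 6 cultures). The bounds hold for that probe alone, since a further probe had means of 31.8 against 557 in normoxia and 47.9 against 834 after 4 h on the deposited scale. No other gene passed in any of the 3 exposures, while 380, 503 and 542 genes had an unadjusted p under 0.05. With the array-set block 146, 135 and 150 genes passed, no more than the 191 to 211 unchanged genes that the blocked fit called in simulated data of this comparison in normoxia, and of all genes Kdm3a alone passed in both fits. With simulated array-set effects the line means recovered 0% of the genes changed 4-fold, though those effects can be too large. In the real data the same fit called 2050 genes for G9a knockout in normoxia. Few calls without the block are not read here as few differences. By list, inhibitors of angiogenesis lay lower and cholesterol synthesis higher after 24 h (adjusted p = 0.0105 and 0.00611, lost at adjusted p = 0.751 for both with an estimated correlation), with 0 members past limma's threshold over all genes and 1 and 0 adjusted over the list alone. Serpinf1 was at -1.56 ± 0.48, Sparc at -0.51 ± 0.19 and Cyp51 at 0.45 ± 0.13, none past the test. Cholesterol synthesis was also higher after 4 h (adjusted p = 0.0139, lost at adjusted p = 0.638 with an estimated correlation). Ehmt2 was at -0.48 ± 0.23 after 24 h (adjusted p = 0.877). Without JMJD1a KO1 788 genes passed at 24 h and without WT1 610 passed at 4 h; without either knockout line Kdm3a no longer passed in normoxia and 0 genes did in limma (216 and 208 at an unadjusted p under 0.05). At 24 h 0 passed without JMJD1a KO2, WT1 or WT2, with 740, 585 and 428 at an unadjusted p under 0.05.

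G9a knockout lines differed from wild-type in normoxia in genes of the germline. The cancer-testis genes Magea2 and Magea5 were at the floor in every wild-type culture and at 11.44 ± 0.06 and 11.04 ± 0.17 log2 intensity in G9a knockout cultures (SD, n = 6), at least 123-fold and 93.6-fold higher (adjusted p = 9.5e-05 and 8.0e-04). Magea6 was at least 16.8-fold higher, and the X-linked Xlr4c, named as one of the largest differences, at least 29.5-fold. Of 31 germline genes 15 were higher and none lower (17 and 2 adjusted over the list alone), and 11 were higher with the array-set block as well. The median was 1.32 log2, or 1.23 with genes at the floor set at their bound. The adjusted p was 1.1e-07, lost at adjusted p = 0.229 with an estimated correlation. Of the 2-cell embryo genes 8 of 15 were higher (9 adjusted over the list alone; adjusted p = 1.3e-06, lost at adjusted p = 0.229 with an estimated correlation), 3 with the array-set block as well. Pramel6 was at least 24.9-fold higher, Tcstv3 was higher by 2.99 ± 0.25 (2.40 with the block, adjusted p = 0.0740) and AF067061 by 1.71 ± 0.08 (2.02, adjusted p = 0.0770). On all 12 wild-type arrays of normoxia and 24 h, 11 of the 31 germline genes and 9 of the 15 genes of the 2-cell embryo were at the floor. Such genes were kept for their signal elsewhere and could not come out lower. This favours higher counts and smaller camera p values for both lists.

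Further genes and lists differed in that comparison. Bdh2, a dehydrogenase of ketone body and siderophore metabolism, was lower by -2.67 ± 0.11 (adjusted p = 0.00411), Ccdc114 by -2.53 ± 0.08, the imprinted Phlda2 by -2.35 ± 0.16 and the endothelial Plvap by -2.25 ± 0.11 log2, and the integrin gene Itgb4 at least 4.83-fold (n = 6 and 6 cultures, 2 lines each); all 5 kept their call with the block. Rpl39l (5.70 ± 1.29) was at 1.88 with the block, and the cyclin gene Ccna2 (4.70 ± 1.07) at 0.72 with its call lost (adjusted p = 0.445). Pluripotency had 6 genes higher and 1 lower of 30 (7 and 1 adjusted over the list alone; adjusted p = 0.00335, lost at adjusted p = 0.229 with an estimated correlation and at 0.0575 with the block), with Klf4 at 1.81 ± 0.20 and Nanog at 1.02 ± 0.12 (1.18 and 0.29 with the block, neither passing). Of the 4 Y-linked genes 3 were higher, also adjusted over the list alone (adjusted p = 0.00288, lost at adjusted p = 0.523 with an estimated correlation): Zfy1 was at least 2.77-fold and Kdm5d at least 1.96-fold higher. Eif2s3y did not pass (adjusted p = 0.197), and the wild-type lines stood apart for it in normoxia, at 8.29 in WT1 and at the floor of 4.32 in WT2. Among p53 targets Gadd45a was at -1.62 ± 0.16 and Pmaip1 at -1.78 ± 0.21, and the metallothionein Mt1 was lower, at -1.80 with the block (adjusted p = 4.5e-04). Ehmt2 was at -0.86 ± 0.15 (adjusted p = 0.0312), and at -0.51 with the block (adjusted p = 0.329), and Kdm3a was at 0.41 (adjusted p = 0.0865).

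Of all genes, 643 were higher and 1407 lower in G9a knockout normoxia (3842 at an unadjusted p under 0.05), and 146 and 129 were so with the array-set block as well, which called 451. The blocked fit called many unchanged genes in simulated data of this comparison, so part of its calls can be false. The median of all genes lay at -0.12 log2 here and at 0.03 with the deposited values left unscaled, where 53.9% of called genes were higher in place of 31.4%, so that the excess of lower genes turned with the scaling. With no filter on dim probes 253 genes passed, and with cultures as the replicates 4862 or 6296 did. Without G9a KO1 1142 genes passed, without G9a KO2 561, without WT1 3323 and without WT2 597.

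After 24 h of hypoxia 284 genes were higher and 309 lower in G9a knockout than in wild-type cells (3757 at an unadjusted p under 0.05), and 130 and 84 were so with the array-set block as well. Of the 2-cell embryo genes 12 of 15 were higher (14 adjusted over the list alone), 9 with the block as well; their median was 1.35 log2, or 1.25 with genes at the floor set at their bound (adjusted p = 5.7e-12, lost at adjusted p = 0.129 with an estimated correlation). Pramel6 was at least 20.1-fold, AF067061 at least 8.61-fold and Pramel31 at least 5.32-fold higher, and Tcstv3 was higher by 4.30 ± 0.40 log2 (SE, 2 lines against 2, n = 6 and 6). As in normoxia, 9 of the 15 genes of the 2-cell embryo and 11 of the 31 germline genes were at the floor in wild-type cells. These could not come out lower. Germline genes had 10 of 31 higher (15 and 2 lower adjusted over the list alone; adjusted p = 2.9e-07, lost at adjusted p = 0.228 with an estimated correlation), with Magea2 at least 109.5-fold and Magea5 at least 85.3-fold higher. Pluripotency had 4 of 30 higher (6 and 1 lower adjusted over the list alone) and Y-linked genes 1 of 4 (3 adjusted over the list alone), both lost at adjusted p = 0.582 with an estimated correlation. Dhrsx, a dehydrogenase, was at -2.93 ± 0.17 and the insulin signalling gene Irs2 at -2.27 ± 0.08. Morc1, a germline gene at least 20.7-fold higher, was at 1.11 with the block (adjusted p = 0.0747). Ehmt2 did not pass (adjusted p = 0.0648), and was at -0.66 with the block (adjusted p = 0.175). The median of all genes was -0.13, and 0.05 with the deposited values left unscaled. The share of called genes that were higher was 47.9%, 71.7% with scaling to the 75th percentile and 68.5% with the deposited values. The count of 593 became 98 with no filter on dim probes, 1641 with only probes above the floor on every array, 1382 with trend and robust settings, and 5170 or 6510 with cultures as the replicates. Without WT1 or without WT2 3 genes passed, without G9a KO1 45 and without G9a KO2 72.

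After 4 h 1015 genes were higher and 1980 lower in G9a knockout cells, and 120 and 101 were so with the array-set block as well, which called 326. Magea2 was at least 114.7-fold, Magea5 at least 92.0-fold and Xlr4c at least 33.9-fold higher (2 lines against 2, n = 6 and 6 cultures). Germline genes had 16 higher and 2 lower of 31 (18 and 4 adjusted over the list alone), 2-cell embryo genes 7 of 15 higher (8), pluripotency 8 higher and 3 lower of 30 (the same) and Y-linked genes 3 of 4 higher (3); the calls were lost at adjusted p = 0.178, 0.178, 0.317 and 0.317 with an estimated correlation. Igf2, an imprinted growth factor gene, was at -3.32 ± 0.72 (-1.98 with the block) and Bdh2 at -2.66. The imprinted Cdkn1c was at -2.36 ± 0.44, and at 0.39 with the block, Rhox6 at -2.61 and -0.58, Gabarapl2 at 5.04 and 1.09, and Ccna2 at 4.71 and 0.49; none of these 4 passed with the block. Ehmt2 was at -0.61 ± 0.13 (adjusted p = 0.0326; -0.32 and 0.708 with the block). The median of all genes was -0.14, and 0.02 with the deposited values left unscaled, where 54.2% of called genes were higher in place of 33.9%. With no filter on dim probes 1147 genes passed, and with cultures as the replicates 5082 or 6471 did. Without WT1 4754 genes passed, without G9a KO1 1038 and without G9a KO2 926.

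Whether the 24 h response itself differed between genotypes was tested on the same line means. No gene passed in limma for either knockout, with 228 (Jmjd1a) and 552 (G9a) genes at an unadjusted p under 0.05, and 67 and 370 called with the array-set block. With no filter on dim probes 41 passed for G9a. In simulated G9a data with array-set effects this fit recovered 0% of the genes changed 4-fold and the blocked fit 93.9%, with 4 unchanged genes called. Those simulated effects can be too large. The absence of calls without the block is not read as an absence of differences. The list of 2-cell embryo genes lay higher in G9a knockout lines in this test. Their median difference was 0.74 log2, and 10 of 15 passed adjusted over the list alone (adjusted p = 1.8e-12, lost at adjusted p = 0.319 with an estimated correlation), and 8 of 15 passed over all genes with the block. Of the 15, 9 were at the floor on all 12 wild-type arrays of normoxia and 24 h, among them Pramel31, Arg2 and Tdpoz4, so that a wild-type response of these genes could not be measured and their difference is not given. The other 6 had a median difference of 1.32 log2, and of 1.77 with the block, where 3 of them passed. Cholesterol synthesis responded less in G9a knockout lines (median -0.27, 1 lower adjusted over the list alone; adjusted p = 0.00196, lost at adjusted p = 0.457 with an estimated correlation; 5 lower with the block), as for Cyp51 at -1.06 ± 0.13 (-1.30 with the block, adjusted p = 1.0e-04). In G9a knockout lines p53 targets and the stress response lay higher and mesoderm lower, with 0 and 4 members higher and 2 lower adjusted over the list alone (adjusted p = 0.00128, 0.0156 and 0.0185, lost at adjusted p = 0.319, 0.457 and 0.343 with an estimated correlation). The Y-linked list gave an adjusted p of 0.00227 (0.319 with an estimated correlation), but Kdm5d and Zfy1, 2 of its 4 genes, were at the floor on all 12 wild-type arrays compared and Eif2s3y was so in WT2 normoxia, so no difference in response is read from it. For Jmjd1a, cholesterol synthesis had an adjusted p of 0.0267, lost at adjusted p = 0.614 with an estimated correlation and at 0.499 with the block.

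**Figure D4:**
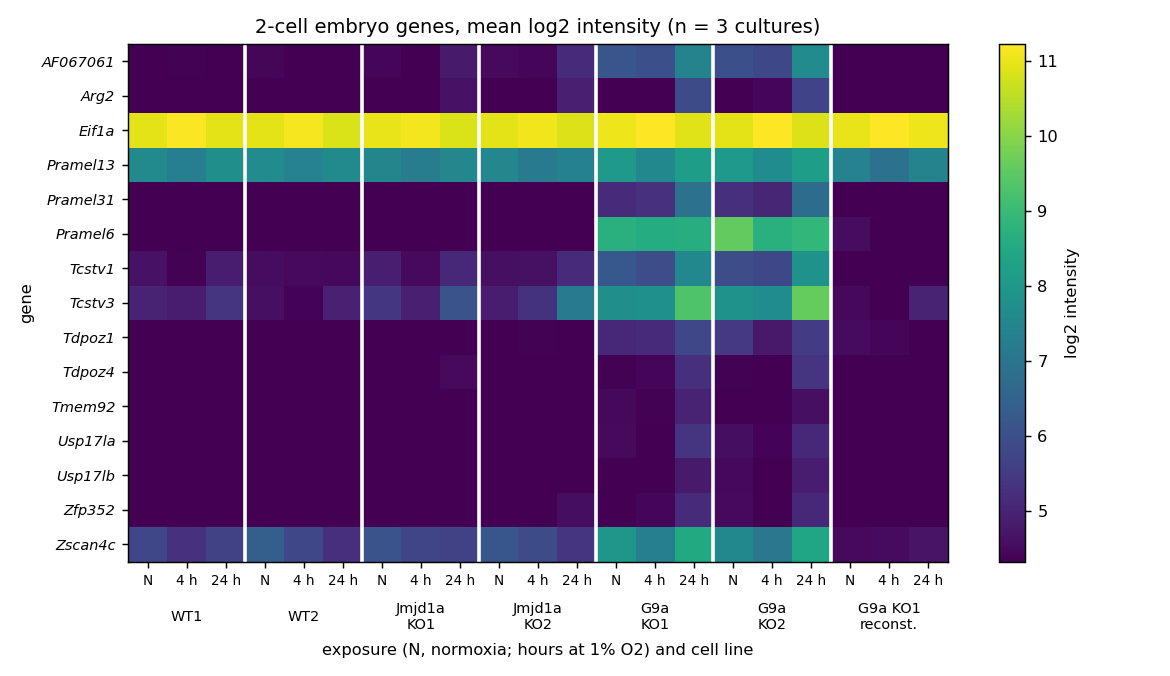
Mean log2 intensity of 15 genes of the 2-cell embryo (vertical axis) in 7 lines under 3 exposures (horizontal axis), 3 cultures each, with the colour scale in log2 units. Of these genes 12 rose and 2 fell with 24 h of hypoxia in G9a knockout cells, and 1 fell in wild-type cells.

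Putting G9a back was read against the parent line G9a KO1. In normoxia the Magea genes lay at the floor again. Magea2 was at least 133.8-fold, Magea5 at least 92.7-fold and Magea6 at least 17.4-fold lower (n = 3 and 3 cultures, 1 line each). Germline genes fell in 18 of 31 cases and rose in 3 (20 and 4 adjusted over the list alone), and 14 fell with the array-set block as well. The median was -0.79, or -0.77 with genes at the floor set at their bound (adjusted p = 7.9e-24, and 3.6e-11 with an estimated correlation). Genes of the 2-cell embryo fell in 8 of 15 cases, also adjusted over the list alone (adjusted p = 3.5e-06, lost at adjusted p = 0.267 with an estimated correlation), 1 with the block as well. Pramel6 was at -4.15 ± 0.14 and Zscan4c at -3.49 ± 0.31 (-3.04 with the block, adjusted p = 0.059). All 4 Y-linked genes fell (adjusted p = 0.0151 with an estimated correlation), with Eif2s3y at -1.32. Bdh2 rose by 2.39 ± 0.14, Ccdc114 by 2.18 and the cyclin gene Ccnd2 by 2.04, and Plvap was at least 3.63-fold higher. Ehmt2 was higher by 0.41 ± 0.13 (adjusted p = 0.0135; 0.42 with the block, adjusted p = 0.640). In all 1296 genes were higher and 1158 lower, of which 138 and 144 also passed with the block, which called 334. In simulated data of this comparison 46.3 to 51.8% of the genes called in both fits were unchanged, so many of these calls can reflect 1 line against another.

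After 24 h of hypoxia 3056 genes were higher and 1787 lower in the reconstituted line, 230 and 243 with the block as well, which called 615, and 50 were called in opposite directions. Genes of the 2-cell embryo fell in 14 of 15 cases (14, with 1 higher, adjusted over the list alone), 7 with the block as well (median -1.48, or -1.41 with genes at the floor set at their bound; adjusted p = 7.2e-13, and 0.0308 with an estimated correlation). Tcstv3 was at -4.36 ± 0.31 and Zscan4c at -3.84 ± 0.31, Pramel6 at least 18.7-fold and Pramel31 at least 5.79-fold lower (n = 3 and 3). Germline genes had 20 lower and 4 higher of 31 (20 and 5 adjusted over the list alone; adjusted p = 5.8e-08 with an estimated correlation), with Magea2 at least 111.6-fold and Xlr4c at least 40.9-fold lower. Aass, a lysine-degrading enzyme gene, was at least 31.5-fold lower, and Dhrsx was higher by 2.47 and Mzb1 by 2.28. Calls for p53 targets (8 lower, 3 higher), cholesterol synthesis (11 higher) and Y-linked genes (4 lower) were lost at adjusted p = 0.154, 0.327 and 0.154 with an estimated correlation. Ehmt2 was higher by 1.06 ± 0.13 (0.33 with the block, adjusted p = 0.512). The share of called genes that were higher was 63.1%, 52.4% with scaling to the 75th percentile and 43.1% with the deposited values. No array set held both lines under 1 exposure, so these differences cannot be told apart from set differences except through the blocked values.

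The reversal was read from G9a KO2 against wild-type set beside reconstituted against G9a KO1, 2 differences that share no array without the array-set block. That fit took cultures as the replicates and called 6084 (normoxia) and 6043 (24 h) of 8740 genes for G9a KO2 against wild-type. These calls do not allow for differences between single lines. In normoxia 489 genes were higher in the knockout and lower after reconstitution, where unrelated calls would give 285. A further 881 went the other way (583 if unrelated), and 123 and 344 were higher or lower in both (319 and 521). After 24 h the counts were 1181, 2166, 192 and 203, against 473, 1304, 809 and 762 if unrelated. With the block, whose set terms are shared by both, 60 genes were higher in the knockout and lower after reconstitution in normoxia, 15 went the other way and 8 and 4 were higher or lower in both, and after 24 h of hypoxia these were 63, 14, 10 and 3. The balance between the first 2 directions thus turned with the block. Without it 2154 genes were called higher and 3930 lower in G9a KO2 in normoxia, and 2315 and 3728 after 24 h. The balance of the counts therefore also follows the number of genes called in each direction. Since sets link the lines in the blocked fit, the blocked counts have no chance value here. Across all 8740 genes, which are not independent replicates, Pearson's r of the log2 differences was -0.306 in normoxia (Spearman -0.222; -0.626 to -0.0393 at single densities) and -0.748 at 24 h (Spearman -0.639; -0.742 to -0.692). With the block r was -0.129 (Spearman 0.0597) and -0.189 (Spearman 0.0154), closer to 0.

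Seeding density changed genes of metabolism and stress over the range tested. Per step of 1 density unit, Chac1 rose by 0.38 ± 0.03, the lipoprotein receptor gene Vldlr by 0.35 ± 0.03, Nupr1 by 0.33 ± 0.03, Vegfa by 0.27 ± 0.02 and Eno2 by 0.25 ± 0.02. Gata2, a haematopoietic transcription factor, fell by 0.20 ± 0.02 and the transglutaminase Tgm1 by 0.18 log2 (SE, 63 cultures). A total of 1311 genes rose and 1544 fell with density, 1227 and 1419 with the array-set block as well. With the deposited values left unscaled 1493 rose and 1319 fell, so the direction of the excess turned with the scaling. Glycolysis had 17 of 19 genes up, also adjusted over the list alone (median 0.05; adjusted p = 0.00329 with an estimated correlation), hypoxia-inducible genes 20 up and 1 down of 32 (21 and 1 adjusted over the list alone; adjusted p = 0.00307 with an estimated correlation) and the stress response 15 up and 2 down of 24 (adjusted p = 0.00866 with an estimated correlation), with Asns at 0.14 ± 0.01. Ribosome biogenesis genes fell in 15 of 24 cases (adjusted p = 1.1e-04 with an estimated correlation), as for Pes1 at -0.06 ± 0.01. Mesoderm genes fell in 5 of 11 cases, with 1 up (adjusted p = 0.0229 with an estimated correlation). Cholesterol synthesis had 10 of 17 up and oxidative phosphorylation 12 up and 2 down of 44, lost at adjusted p = 0.0975 and 0.0849 with an estimated correlation. Adjusted over the list alone the last 5 lists had the same counts.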

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

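The tests with the array-set block, those inside array sets and those of the 3 patterns weighed last were chosen only after the results were seen, and the counts over other splits of the samples were planned before the data were examined.

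Among 72 pairs of group and measure, 1 of 6 cultures lay far from the other 5 in 3 pairs, against 3.6 by chance (1 in 20). JMJD1a KO2 at density 6 after 4 h had 43.9% of probes above the floor. Its array set had a mean of 43.8%, the sets of the other 5 cultures 42.0 and 42.5%. Pou5f1 was at 12.24 log2 in JMJD1a KO1 at density 4 after 4 h. Nanog was at 12.98 in G9a KO2 at density 2 in normoxia.

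The 24 h response of some lists passed the test of the difference between genotypes. Cholesterol synthesis differed between Jmjd1a knockout and wild-type lines (adjusted p = 0.0267, 0.614 with an estimated correlation and 0.499 with the array-set block). Between G9a knockout and wild-type lines this test passed for the 2-cell embryo genes (1.8e-12), mesoderm (0.0185), p53 targets (0.00128), the stress response (0.0156), cholesterol synthesis (0.00196) and Y-linked genes (0.00227), and with an estimated correlation these 6 adjusted p values were 0.319, 0.343, 0.319, 0.457, 0.457 and 0.319. With the array-set block they were 3.6e-10, 0.605, 0.0032, 0.0495, 2.0e-10 and 1.2e-05. Of the 2-cell embryo genes 9 of 15, of the Y-linked genes 2 of 4 and of the p53 targets 2 of 20 were at the floor on all 12 wild-type arrays compared, and a wild-type response of these could not be measured. No difference in response is read from the Y-linked list.

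Chance can be excluded for the hypoxia comparisons of the 2-line genotypes and for density. Only the real split of the samples (1 of 100) gave as many genes. In both knockouts at 24 h that split followed array set in each line, so sets are not excluded. The real counts and the highest of the other splits were 2225 and 40 for wild-type at 24 h, 2572 and 7 at 4 h, 1431 and 587 between 4 h and 24 h, 2691 and 33 for Jmjd1a knockout at 24 h, 1976 and 3 at 4 h, 4108 and 6 for G9a knockout at 24 h, 3043 and 6 at 4 h, and 2855 and 1 for density. The split with 587 genes nearly followed line and array set. With the array-set block 2208 genes were called between 4 h and 24 h, 1759 of them also without it. Splits were too few for a share under 0.05 elsewhere. The reconstituted line had 10 splits, all with 0 genes at 24 h and at 4 h in limma on 6 arrays. The real split had 2461 and 2237 at an unadjusted p under 0.05. Reconstituted against parent also had 10 splits, with 224 genes and 0 in normoxia and 4452 and 0 at 24 h. Knockout against wild-type had 3 splits of 4 lines: the real counts were 1, 1 and 1 for Jmjd1a and 2050, 2995 and 593 for G9a in normoxia, 4 h and 24 h, and the highest other was 0 each time. For the difference in response, all 3 splits gave at least the real count of 0, in limma, with 228 genes for Jmjd1a and 552 for G9a at an unadjusted p under 0.05. The highest other was 525 for Jmjd1a, where the 2 lines numbered 1 stood against the 2 numbered 2, which points to a structure of the samples, and 0 for G9a.

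Many genes differed between G9a knockout and wild-type lines in normoxia, with 2050 called, and 451 were called with the array-set block. In simulated data of this comparison the blocked fit also called many unchanged genes. A difference in normalization between arrays is argued against as the cause of the number of calls, since the lowest count under the other scalings was 1821, 1408 of them also called here, but not of their direction, since 643 higher and 1407 lower genes became 981 and 840 with the deposited values. Of the 275 genes called in both fits, 89.8% kept their direction in G9a KO2 against reconstituted cells in hypoxia linked inside array sets. Their median there was 0.58 log2 against a called size of 1.33. The blocked fit that helped choose these genes used all 63 arrays, these hypoxia arrays among them, which favours a kept direction. G9a KO2 was also 1 of the 2 knockout lines of the call. The share therefore cannot by itself exclude the array set as a cause, and it can have added to their size. The linked comparison had 6 hypoxia arrays on each side, and the link rested on 2 reconstituted normoxia arrays in 1 set and 1 in the other. For the 1774 genes called without the block alone, 71.1% kept their direction with a median of 0.17 against a called size of 0.77, where 59.3% of all genes did. For these, array set and genotype cannot be told apart, because no set held G9a knockout and wild-type arrays, and both may contribute.

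In G9a knockout lines 15 of 31 germline genes were higher in normoxia (adjusted p = 1.1e-07, lost at adjusted p = 0.229 with an estimated correlation). In the comparison linked inside sets the 15 called genes had a median of 2.89 log2, against 3.13 as called. With genes at the floor set at their bound the called median was 3.07. A difference between array sets is argued against for the 8 Magea and Xlr genes and Asz1, which kept most of their called size there. Sohlh2 was at 0.82 there against 0.71 as called, and Smc1b at 1.76 against 3.13. Stk31 was at 1.08 against 2.23, Sycp1 at 0.66 against 1.40, Tuba3a at 0.50 against 1.60 and Ddx4 at -0.55 against 2.38. For Smc1b and the genes given after it, a share of the array set stays open. Loss of G9a is a candidate cause. The same genes had a median of -2.63 in the reconstituted line against its parent with the array-set block. The normoxia arrays of the parent, G9a KO1, were among those that chose the genes, which favours a negative value. The linked comparison set G9a KO2 against reconstituted cells in hypoxia, on arrays that took no part in the call. Signal shared among the called genes is argued against for the 7 with no other called gene of the same letters in its symbol. Their values with the block ran from 0.26 log2 (Stk31, 2.23 as called) to 3.34 (Asz1, 3.36 as called). Signal from related genes that were not called stays open for these 7. For the 8 Magea and Xlr genes shared signal of any kind stays open, since no probes were tested against each other.

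The 2-cell embryo genes were higher after 24 h than after 4 h of hypoxia in G9a knockout lines, with a median of 0.88 log2. Of 15 genes 13 rose, among them Tcstv1 by 1.82 ± 0.22 and Zscan4c by 1.28 ± 0.22 (SE, n = 6 and 6), Eif1a fell by 0.35, and Pramel6 was at 0.10 and did not pass. A difference between array sets is argued against by medians of 0.97 in G9a KO1 and 0.80 in G9a KO2 inside 1 set each. More crowded cultures are argued against by a median of 0.12 between the highest and lowest density. Signal shared within 1 gene family is argued against by the 9 families, told apart by symbol, among those that rose. Probes were not compared, so other shared signal stays open. Medians in the other lines ran from 0 to 0.01, where many members lay at the floor, and Tcstv3 went from 5.34 to 7.16 log2 intensity in JMJD1a KO2 and from 4.92 to 6.10 in JMJD1a KO1 (n = 3 and 3 cultures), with 8 of 15 members higher inside a set in JMJD1a KO2. Whether the rise depends on the loss of G9a therefore stays open, and the test of the difference in the 24 h response gave an adjusted p of 0.319 with an estimated correlation, with 9 members at the floor on all wild-type arrays compared.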

How the results depend on the processing

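The array-set block and the fit without the array with a second floor were chosen only after the results were seen; the other settings were planned. Of the counts and Pearson correlations, 214 stayed close to the reported value and 76 moved. Close meant within 1.5 times for a count. For a correlation it meant within the SD over the densities, 0.333 in normoxia and 0.0251 at 24 h. Only a correlation could be scored as reversed, and 0 were. The balance of higher and lower genes within a count was not scored. The Spearman correlations of the reversal changed sign with the array-set block, to 0.0597 in normoxia and 0.0154 at 24 h. For the named genes, 2667 values kept direction and side of the threshold, 161 lost their call, 21 gained one and 2 reversed, both with the array-set block: Zfp987 at 24 h in the reconstituted line (0.066) and Cdkn1c in G9a knockout against wild-type at 4 h (0.39). For the list calls 132 were kept, and 72 lost, 54 of them with an estimated correlation and 18 with the array-set block. The cause was not tested.

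With the array-set block the counts were 1327 for Jmjd1a knockout at 24 h, 1732 and 1045 for G9a knockout at 24 h and 4 h, and 1743 and 1350 for the reconstituted line. They were 146, 135 and 150 for Jmjd1a knockout against wild-type in normoxia, 4 h and 24 h, 451 and 326 for G9a knockout in normoxia and 4 h, 67 and 370 for the difference in response (Jmjd1a, G9a), and 334 and 615 for reconstituted against parent, with r = -0.189 for the reversal at 24 h. With cultures as the replicates and density as a replicate block, Jmjd1a knockout against wild-type gave 154, 175 and 533 genes with line as a random block and 1114, 1366 and 2951 with lines fixed, in normoxia, 4 h and 24 h. G9a knockout gave 4862, 5082 and 5170, and 6296, 6471 and 6510, and the difference in response 619 and 1218 with lines fixed. Line and density pairs as a replicate block gave 2738 and 1591 for Jmjd1a knockout at 24 h and 4 h and 1400 and 1185 for the reconstituted line. On the arrays compared alone the reconstituted line gave 0 and 0 in limma (2461 and 2237 at an unadjusted p under 0.05), with fewer arrays for the variance.

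With no filter on dim probes, G9a knockout against wild-type gave 253, 1147 and 98 genes in normoxia, 4 h and 24 h, Jmjd1a knockout 5 at 4 h and 4 at 24 h, and the difference in response for G9a 41. With only probes above the floor on every array, Jmjd1a knockout gave 2 and G9a knockout 1641 genes at 24 h, and the reversal at 24 h r = -0.665. Scaling to the 75th percentile gave 3 for Jmjd1a knockout at 24 h, and eBayes with trend and robust settings 1382 for G9a knockout at 24 h. Across these settings all counts of the wild-type hypoxia comparisons and of density stayed within 1.5 times the reported ones. With the deposited values some excesses of lower genes turned. Wild-type cells at 24 h then had 1723 genes higher and 1479 lower. Jmjd1a knockout cells had 2185 and 2014 at 24 h and 1384 and 1200 at 4 h. G9a knockout cells had 2198 and 1804 at 24 h and 1532 and 1515 at 4 h, and density gave 1493 and 1319.

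Leaving out 1 line, or 1 density for the reconstituted line, where a lone line is assumed to vary like the others, moved further counts. Without WT1 and WT2 in turn, wild-type cells gave 1407 and 1249 genes at 4 h and 2552 and 1478 between 4 h and 24 h. Without KO1 and KO2 in turn, Jmjd1a knockout cells gave 5005 and 2550 at 24 h and 1606 and 1490 at 4 h, and G9a knockout cells 2469 and 3434, and 2051 and 1893. Without density 2, 4 and 6, the reconstituted line gave 2118, 1966 and 3858 at 24 h and 1810, 1806 and 3858 at 4 h. Without KO1, KO2, WT1 and WT2 in turn, G9a knockout against wild-type gave 1142, 561, 3323 and 597 in normoxia, 1038, 926, 4754 and 3205 at 4 h, and 45, 72, 3 and 3 at 24 h. Jmjd1a knockout against wild-type gave 0, 0, 1 and 1, then 1, 1, 610 and 1, then 788, 0, 0 and 0 in the same order. These 0 counts are from limma, with 216 and 208 genes in normoxia and 740, 585 and 428 at 24 h at an unadjusted p under 0.05. For the difference in response, every left-out line gave 0 in limma, with 174 to 1602 genes for Jmjd1a and 388 to 499 for G9a at an unadjusted p under 0.05. Background correction of the raw signals with negative controls, detection p filters and the chip as a random block were not run, since no label ties the raw columns to samples or a sample to a chip. Genes at the floor, 20 on the deposited scale, carry no measure of their level, which limits what can be said of weak transcripts.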

Other observations

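Hif1a, the interferon-inducible genes and the array-set block were chosen only after the results were seen.

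Hif1a encodes the oxygen-regulated subunit of the hypoxia-inducible factor, and its transcript fell in each genotype. After 4 h it was at -0.62 ± 0.10 log2 in wild-type, -0.90 ± 0.10 in Jmjd1a knockout, -0.98 ± 0.10 in G9a knockout (SE, n = 6 and 6 each) and -0.82 ± 0.15 in reconstituted cells (SE, n = 3 and 3). After 24 h it was at -1.07 ± 0.10 in wild-type, -1.55 ± 0.10 in G9a knockout and -1.28 ± 0.15 in reconstituted cells. With the array-set block the 24 h values were -0.95, -1.49 and -1.42, and -1.51 in Jmjd1a knockout cells. The adjusted p was under 0.05 in all 8 comparisons with and without the block. The 24 h response differed from that of wild-type cells by -0.42 ± 0.15 in Jmjd1a knockout and -0.48 ± 0.15 in G9a knockout cells, neither of which passed the test of the difference (adjusted p = 1 and 0.650, and 0.394 and 0.266 with the array-set block).

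Some interferon-inducible genes rose in hypoxia, in part already at 4 h. Gbp2 rose by 0.41 ± 0.10 log2 after 4 h and 1.94 ± 0.10 after 24 h in wild-type cells (SE, n = 6 and 6 each). G9a knockout cells gave 1.19 ± 0.10 and 2.97 ± 0.10, or 0.40 (adjusted p = 0.246) and 2.20 with the array-set block. The SE leaves out line differences (SD of Gbp2 in G9a knockout normoxia 1.48). Gbp3 was at 0.28 ± 0.14 (adjusted p = 0.155) and 1.78 ± 0.14 in wild-type cells. G9a knockout cells had 0.68 ± 0.14 and 2.67 ± 0.14 (1.86 at 24 h with the block). Ifi47 rose by 2.64 ± 0.23 after 4 h and by 3.74 ± 0.23 after 24 h in G9a knockout cells (1.88 and 2.83 with the block). It was at the floor in reconstituted normoxia and at least 4.68-fold higher after 4 h and 5.27-fold after 24 h. Irf1, a transcription factor of the interferon response, rose by 0.87 ± 0.08 in wild-type, 0.80 ± 0.08 in Jmjd1a knockout, 1.20 ± 0.08 in G9a knockout and 0.84 ± 0.11 in reconstituted cells after 24 h. No list of interferon genes was tested.

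A further Kdm3a probe kept some signal in Jmjd1a knockout cells, at a mean of 31.8 in normoxia and 47.9 after 4 h on the deposited scale, and between 49.0 and 59.4 after 24 h, where wild-type cells had means of 557, 834 and 711 (n = 6 cultures each). Against the floor of 20 it was above it in each of the 18 knockout cultures. A further Ehmt2 probe was above the floor in every group. In wild-type normoxia, 4 h and 24 h its means on the deposited scale were 312, 432 and 693. They were 189, 311 and 339 in G9a knockout and 265, 443 and 516 in reconstituted cells. The third Ehmt2 probe had group means between 20 and 25.7 and carries no measure of G9a. The G9a KO2 culture at density 2 after 4 h of hypoxia had a second tied low value of 21.9, shared by 9339 probes, beside 5204 probes at 20.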
